A study of Homo sapiens with 6 samples.

How the data were processed

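Gene expression was measured in Hut78 cells, an established human T cell line derived from cutaneous T cell lymphoma. Total RNA was hybridised to Affymetrix whole-transcript gene arrays, per the labels' protocols. There were 6 arrays, 3 of untreated cells and 3 of cells given CSH18, a compound given here by its code name. Groups were taken from the treatment label of each sample. The labels disagree about the dose. The titles carry 2 µM for CSH18 replicate 1 and 6 µM for CSH18 replicates 2 and 3, whereas the treatment protocol states 250 nM for 30 h. It also speaks of duplicates, while each group has 3 arrays. Doses are therefore given as the titles' doses. The titles also carry serial numbers, which are 1, 2 and 7 for untreated replicates 1, 2 and 3, and 8, 9 and 10 for CSH18 replicates 1, 2 and 3. No label names a batch. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

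The deposited values were linear intensities, 1 per probe set and array, for 53617 probe sets. Affymetrix Expression Console was used, per the submitters' processing notes, which give no version. The name of the deposited table refers to the iterPLIER summary of probes into probe sets. The background correction, the normalization between arrays and the genome build are not given in the sources used here, so no coordinates are printed. The median intensity per array lay between 69.4 and 77.5, and no array was identical to another. A second deposited table held the same intensities to within 0.05 and was not analysed separately. Summarised intensities carry no count of molecules, so the precision was limited by the number of arrays.

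Probe sets were named through a platform annotation, which gave 1 gene symbol for 16098 probe sets, several for 0, and none for 37519, which are unnamed here rather than without a gene. All 16098 symbols equalled the current RefSeq symbol of their gene ID. For the 779 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used, which left 14884 genes. Intensities were transformed to log2 after adding 16, so fold changes are on the log2(value + 16) scale and understate the change of dim genes. No filter on dim genes was applied.

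CSH18 was compared with untreated cells with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all genes. A second limma fit had 3 groups (untreated, 2 µM and 6 µM in the titles). Its 2 µM group is 1 array, which was assumed to vary like the other groups. TNF and MAPK12 were also tested with a two-sided exact permutation test, whose smallest possible p is 0.1. Of 29 gene lists, the 26 with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and limma's fry were run beside it. Tables were read with the data.table package, version 1.17.8, and plots were drawn with matplotlib 3.10.9.

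The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the 12 largest rises and the 12 largest falls among genes past the threshold with no overlap between groups. Where fewer passed, the places went to genes of that direction with the smallest unadjusted p, which are said not to pass. It also named TNF, MAPK12, up to 4 members per list with the smallest p, and the 5 largest changes each way per dose contrast. A planned list of olfactory receptor genes was not tested, because only 1 named gene, OR4C45, had such a symbol.

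The procedure was tested on simulated data for the 14884 genes, with 100 genes changed per size, all drawn from genes brighter than the median. Noise was drawn independently for each gene and array, with a serial number term added only for the covariate fit. The shares recovered therefore do not speak for dim genes, nor for an array that stands apart at many genes. For CSH18 against untreated, 56% of genes changed by log2 1 and 95% of those changed by log2 2 were recovered. The shares were 38% and 91% for 6 µM against untreated, 18% and 76% for 2 µM against untreated, and 14% and 69% for 6 µM against 2 µM. With the serial number (1 and 2 against 7 to 10) as a covariate they were 6% and 71%. All CSH18 arrays have serial numbers 7 to 10, so that fit sets them against untreated replicate 3 alone. Its serial number term is untreated replicate 3 minus the mean of untreated replicates 1 and 2. The simulated noise took the spread left by the 3-group fit, which includes that distance. The shares for the covariate fit may therefore be too low. Alternatives were offsets of 1 and 64, quantile normalization, median centring, removal of the dimmest 33% or 50% of genes, eBayes without trend or robust, the mean over probe sets, all probe sets, a test per gene without shared variance, the serial number covariate, and leaving out each array.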

Results

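Expression of 14884 named genes was measured on 6 arrays of Hut78 cells, 3 untreated and 3 given CSH18. The labels name p38γ, the kinase encoded by MAPK12, as the target of CSH18, and TNF as a gene of interest downstream. The median intensity was 77.5, 71.5 and 69.4 on untreated replicates 1, 2 and 3, and 70.8, 70.6 and 71.8 on CSH18 replicates 1, 2 and 3. On the first principal component, which held 45.6% of the variance, untreated replicates 1 and 2 lay at -35.0 and -22.4 and untreated replicate 3 at 26.2. CSH18 replicates 1, 2 and 3 lay between them, at 20.2, 1.31 and 9.72. Untreated replicates 1 and 2 carry the serial numbers 1 and 2 in their titles, and the other 4 arrays carry 7 to 10.

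The first comparison asked which genes differed between CSH18-treated and untreated cells. Genes of the integrated stress response, through which the transcription factor ATF4 raises amino acid synthesis and tRNA charging, were higher after CSH18. TRIB3, a pseudokinase induced by ATF4, rose from 9.96 ± 0.33 (SD, n = 3) to 11.70 ± 0.37 on the log2 scale, a 3.33-fold rise. SESN2, a stress-induced regulator of mTORC1, rose by 1.98 on the log2 scale, ATF3 by 1.92 and ATF5 by 1.81. In the other direction, HSPA1A and HSPA1B, which encode nearly identical inducible HSP70 chaperones and are uncertain as separate measurements, both fell by 1.03. In all, 40 genes passed the limma threshold, 38 higher and 2 lower.

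Of the 28 measured genes of the ATF4 and integrated stress response list, 16 passed, all higher, and 24 were higher when adjusted over the list alone. The list mean difference was 0.88, with 26 members positive. The adjusted p of camera was 3.2e-47 with the preset correlation, and adjusted p = 0.14 with an estimated correlation. The genes included the transcription factor ATF4 itself (0.59, SE 0.12), the pro-apoptotic factor DDIT3 (1.48, SE 0.26), asparagine synthetase ASNS (1.08) and the serine synthesis enzymes PHGDH and PSPH (0.97 for PSPH). The tRNA synthetases WARS1 (0.90), AARS1 (0.76), CARS1 (0.70) and GARS1 (0.64) also rose. The other list genes past the threshold were STC2 (1.65), PCK2 (1.15) and VLDLR (1.89). VLDLR lay at 6.19, 6.06 and 8.34 on untreated replicates 1, 2 and 3, and lost its call without untreated replicate 1 or 2, at 1.56 and 1.49, as did STC2 (1.36 and 1.49) and DDIT3 (1.31 and 1.28).

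The largest rises outside this list were PLEK (1.72, SE 0.22), NHSL1 (1.70), ULBP1 (1.59), ANXA3 (1.57) and the non-coding RNA LINC01686 (1.47). ANXA3 lay at 8.07, 8.25 and 9.53 on untreated replicates 1, 2 and 3, and did not pass without untreated replicate 1 or 2 (1.29 and 1.38), nor with the serial number covariate (0.66, limma adjusted p 0.17). NHSL1 and LINC01686 had 1.09 and 1.23 with the covariate and did not pass there either. LINC01686 also did not pass without untreated replicate 2 (1.43). ULBP1 encodes a ligand of the natural killer cell receptor NKG2D. TRIB3 had the smallest adjusted p in limma, 1.4e-05, and VLDLR the highest among the 12 largest rises, 0.015. Only HSPA1A and HSPA1B passed among the falls. The places left by the naming rule went to SRSF5, TIPARP, PLK1, CLK1, LMNA, CDC20, KIF20A, SBNO1, AHNAK and DDX6, which did not pass, with differences from -1.20 (LMNA) to -0.56 (DDX6) and limma adjusted p from 0.065 to 0.14. LMNA lay at 8.07, 8.22 and 6.71 on untreated replicates 1, 2 and 3, and between 6.39 and 6.54 on the CSH18 arrays. With the serial number covariate LMNA, TIPARP and DDX6 had -0.25, -0.26 and -0.27, whereas CLK1 had -0.78 and passed. SRSF5, PLK1, CDC20, KIF20A, SBNO1 and AHNAK had -0.40 to -0.95 there and did not pass. All the genes in these places passed without untreated replicate 3, where LMNA had -1.68. There 1358 genes passed in all, and the untreated arrays left are serial numbers 1 and 2, so CSH18 cannot be told from the serial number. SRSF5, PLK1, CDC20 and KIF20A also passed without CSH18 replicate 1 (-1.12, -1.42, -1.38 and -1.41).

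The count depended on single arrays. It was 11, 14 and 1358 without untreated replicate 1, 2 and 3, and 23 without CSH18 replicate 2, and the ATF4 list then held 4, 6, 24 and 10 of the genes past the threshold. With the serial number as a covariate, which leaves untreated replicate 3 as the only untreated array compared within serial numbers 7 to 10, 51 genes passed. Of the 40 genes, 13 passed again. These included TRIB3, ATF5, SESN2, ATF3, ASNS, PSPH and ATF4, 7 genes of the ATF4 list, and HSPA1A and HSPA1B. The list mean fell to 0.57, with an adjusted p = 0.40 with an estimated correlation, and SESN2 and ASNS to 1.16 and 0.63. Genes that did not pass with the covariate included VLDLR (0.42), STC2 (0.74), DDIT3 (0.72) and AARS1 (0.38). Among the 4 arrays with serial numbers 7 to 10 alone, 0 genes passed in limma, and 1132 had an unadjusted p under 0.05. The differences were those of the covariate fit, with an ATF4 list mean of 0.57, and only the arrays behind the spread were fewer.

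**Figure D1:**
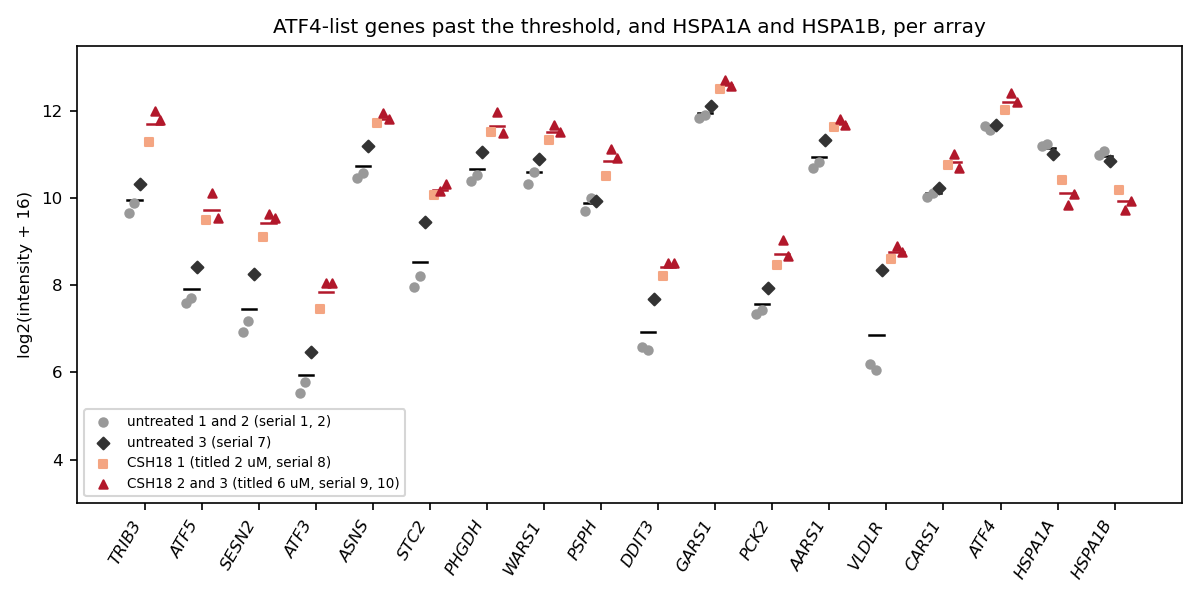
Level of each gene, as log2(intensity + 16), on each array, for the 16 ATF4 list genes past the threshold and for HSPA1A and HSPA1B. Grey and black points are untreated arrays, coloured points are CSH18 arrays, and lines are group means of 3 arrays; untreated replicate 3 lay nearest to the CSH18 arrays for genes such as VLDLR, STC2 and DDIT3.

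Of the 26 gene lists tested, 9 passed with the preset correlation and 0 with an estimated correlation. In the heat shock list, 2 of 13 measured genes fell (HSPA1A and HSPA1B) and 12 were negative, with a mean of -0.32, a camera adjusted p of 2.0e-06 and an adjusted p = 0.14 with an estimated correlation. It was the only one of the 26 lists with an adjusted p under 0.05 in fry, 0.014, which became 0.19 with the serial number covariate. All 29 measured genes of the DNA replication and G1/S list were positive and none passed singly, with a mean of 0.26 and a camera adjusted p of 3.0e-10. Its adjusted p = 0.48 with an estimated correlation. RRM2, a ribonucleotide reductase subunit, had 0.50 (0.24 with the serial number covariate), and CDC45, TYMS and MCM10 had 0.51, 0.42 and 0.43. The list mean was 0.40 without CSH18 replicate 1. Of 43 mitotic genes, 34 were negative and none passed singly, with a mean of -0.24, a camera adjusted p of 1.2e-07 and an adjusted p = 0.48 with an estimated correlation. Their mean was -0.38 without CSH18 replicate 1 and -0.13 without CSH18 replicate 3.

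Hypoxia and glycolysis genes had a mean of 0.26, with VEGFA (1.13) the 1 of 17 that rose, a camera adjusted p of 0.00048 and an adjusted p = 0.57 with an estimated correlation. This list separated the untreated arrays. Its median relative to the untreated mean was -0.40, -0.22 and 0.56 on untreated replicates 1, 2 and 3, and 0.49, 0.059 and 0.13 on CSH18 replicates 1, 2 and 3. With the serial number covariate VEGFA had 0.56 and did not pass, and the list mean turned to -0.39, with a camera adjusted p of 1.6e-09 and an adjusted p = 0.82 with an estimated correlation. Its mean was 0.58 without untreated replicate 3, and the call was lost without untreated replicate 1, untreated replicate 2 or CSH18 replicate 1, at 0.060, 0.13 and 0.15. Cholesterol synthesis and SREBP2 target genes had a mean of -0.16, none of 18 passing singly, with a camera adjusted p of 0.0080 and an adjusted p = 0.57 with an estimated correlation. Untreated replicate 3 lay at a median of 0.36 and untreated replicates 1 and 2 at -0.27 and -0.037. With the covariate the mean was -0.48, with an adjusted p = 0.40 with an estimated correlation, and 5 genes fell, MSMO1, HMGCS1, IDI1, INSIG1 and SQLE. The mean was -0.29 without untreated replicate 1, and the call was lost without untreated replicate 3 or CSH18 replicate 2, at 0.00093 and -0.12. All 20 ribosome biogenesis genes among MYC targets were negative, with a mean of -0.24, none passing singly, a camera adjusted p of 2.0e-06 and an adjusted p = 0.48 with an estimated correlation. Their mean was -0.14 without untreated replicate 2 and -0.38 without untreated replicate 3, and turned to 0.043 with the covariate.

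NF-κB targets of TNF signalling had a mean of 0.12 and none of 33 passing singly, with a camera adjusted p of 0.024 and an adjusted p = 0.35 with an estimated correlation. The call was lost without untreated replicate 1 or CSH18 replicate 1, at 0.091 and 0.12. ICAM1 had 0.75 and BCL2A1 0.84, which became 0.31 and -0.07 with the serial number covariate. Interferon-stimulated genes had a mean of 0.11 and none of 29 passing singly, with a camera adjusted p of 0.031 and an adjusted p = 0.48 with an estimated correlation. The call was lost without untreated replicate 1 or 3, at 0.066 and 0.12, and without CSH18 replicate 1 or 3, at 0.13 and 0.095. XAF1 had 0.56 and RSAD2 -1.08, which became 0.71 (limma adjusted p 0.017) and 0.34 with the serial number covariate. RSAD2 lay at 9.68, 9.87 and 7.63 on untreated replicates 1, 2 and 3, and between 7.83 and 8.14 on the CSH18 arrays. With the serial number covariate neither list passed.

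The other 17 lists did not pass, with camera adjusted p of 0.0895 or more. They were the p38 kinases, TNF receptors, AP-1 and immediate early genes, T cell receptor signalling, T cell cytokines and chemokine receptors, genes described as raised in cutaneous T cell lymphoma, p53 targets, apoptosis regulators, unfolded protein response chaperones, NRF2 targets, metallothioneins, autophagy and lysosome genes, and olfactory signalling partners. Markers of B cells, myeloid cells, natural killer and cytotoxic cells, and keratinocytes and fibroblasts did not pass either. Single members rose within some of these, ATF3 in the AP-1 list, SESN2 in the p53 list, and PMAIP1 (0.90, and 0.60 with the covariate, where it did not pass), which encodes the BH3-only protein NOXA, in the p53 and apoptosis lists. Replication-dependent histones (0 measured genes), TNF superfamily ligands (3) and erythroid and platelet markers (3) had too few genes to test. OR4C45, the 1 named olfactory receptor, had -0.27 (limma adjusted p 0.83), and 0.026 with the serial number covariate.

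**Figure D2:**
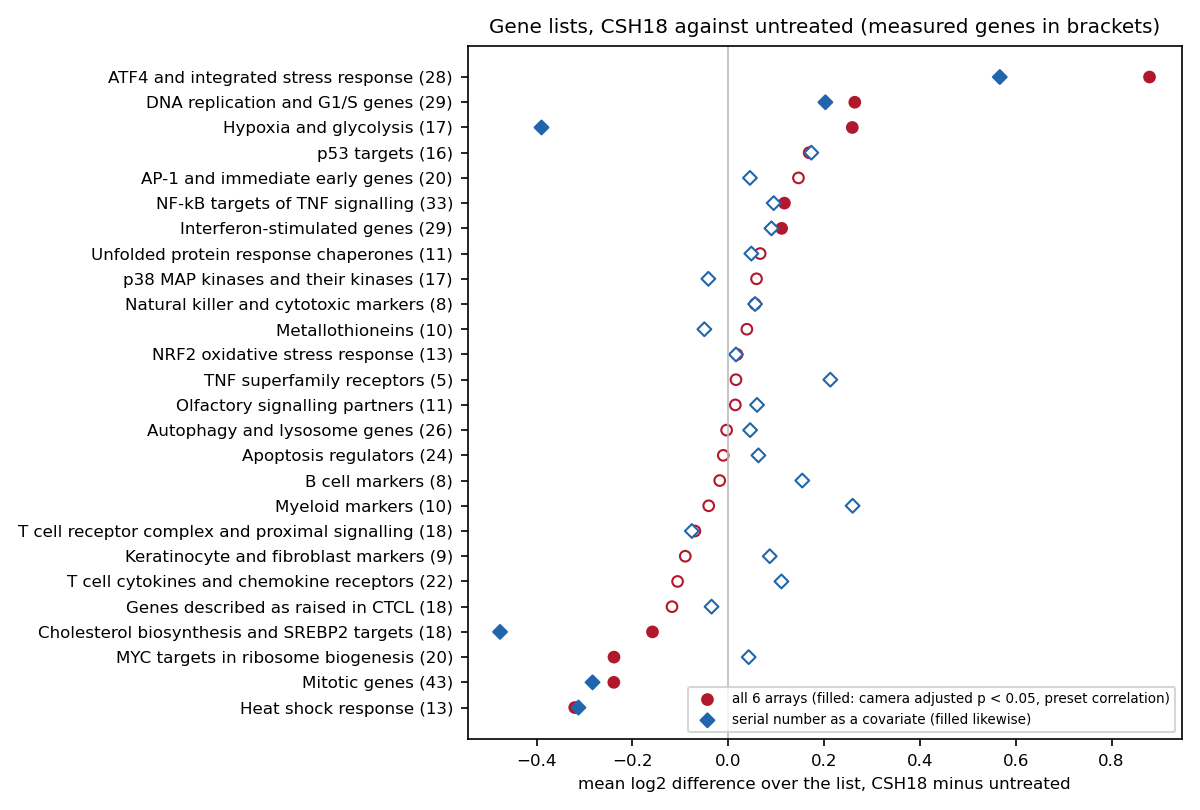
Mean log2 difference of each gene list, CSH18 minus untreated, over all 6 arrays (red circles) and with the serial number as a covariate (blue diamonds), filled where camera with the preset correlation had an adjusted p under 0.05. The ATF4 list lay at 0.88 and 0.57, and the hypoxia and glycolysis list at 0.26 and -0.39.

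For the labels' question about TNF and p38γ, the arrays gave the RNA of both genes only. RNA of MAPK12 does not measure the activity of p38γ, and RNA of TNF does not measure TNF protein. TNF was 8.58 ± 0.55 (SD, n = 3) in untreated cells and 8.52 ± 0.20 after CSH18. The difference of -0.06 (SE 0.22) was smaller than the spread between untreated arrays, with a 95% interval from -0.52 to 0.40 and a limma adjusted p of 0.96. The exact permutation p was 0.9, where 0.1 is the smallest that 3 against 3 arrays allow. Of the 8 TNF probe sets, 7 held identical values on every array and so repeat the same reading, -0.06. The remaining probe set had 0.03. The sign depended on single arrays, with 0.25 without untreated replicate 3 and 0.05 without CSH18 replicate 2. TNF lay at 8.18, 8.35 and 9.20 on untreated replicates 1, 2 and 3, and between 8.29 and 8.66 on the CSH18 arrays. With the serial number covariate, which sets CSH18 against untreated replicate 3 alone, the difference was -0.69. That value rests on the highest of the untreated arrays. The TNF superfamily ligands CD70 and EDA had differences of 0.04 and 0.21, and -0.20 and 0.13 with the covariate.

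MAPK12 was 7.15 ± 0.35 (SD, n = 3) in untreated cells and 7.45 ± 0.12 after CSH18. The difference of 0.30 had a 95% interval from -0.17 to 0.76, a limma adjusted p of 0.79 and an exact permutation p of 0.3. It turned to -0.11 with the serial number covariate. Of the other p38 pathway genes, MAP2K6 had 0.43, MAPKAPK3 -0.31, TAB1 -0.30 and MAPKAPK2 -0.19, none passing. MAP2K6 had 0.078 and MAPKAPK2 -0.06 with the covariate.

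The second set of comparisons separated the titles' doses. At 6 µM, 7 of 43 mitotic genes fell relative to untreated cells, and the list had a mean of -0.38. Its camera adjusted p was 1.3e-19, with an adjusted p = 0.20 with an estimated correlation. PLK1, a kinase that drives mitotic entry, fell by 1.42 on the log2 scale, KIF20A, a kinesin of cytokinesis, by 1.41, and CDC20, an activator of the anaphase-promoting complex, by 1.38. HMMR, AURKA, CCNB1 and CENPA fell too. The ribonucleotide reductase subunit RRM2 rose by 0.64, and all 29 DNA replication genes were positive, with a mean of 0.40, a camera adjusted p of 9.4e-20 and an adjusted p = 0.26 with an estimated correlation. The ATF4 list rose as in the first comparison, with 16 of 28 genes passing (camera adjusted p 1.4e-50, adjusted p = 0.20 with an estimated correlation) and SESN2, ATF3, PLEK, VLDLR and TRIB3 the 5 largest rises of the contrast (2.14, 2.13, 1.98, 1.97 and 1.94). VLDLR did not pass without untreated replicate 1 or 2 (1.63 and 1.57), nor with the serial number covariate (0.49). HSPA1A and HSPA1B fell by 1.18 and 1.15. At this dose 6 of the 26 lists passed camera with the preset correlation and 0 with an estimated correlation. They included heat shock (-0.35), cholesterol synthesis (-0.21) and MYC ribosome biogenesis (-0.20). The 7 mitotic genes became 3 without untreated replicate 1, untreated replicate 2 or CSH18 replicate 3, and 18 without untreated replicate 3. The 16 ATF4 list genes became 5, 5 and 24 without untreated replicate 1, 2 and 3, and 8 without CSH18 replicate 2.

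In all, 57 genes passed at 6 µM, 46 higher and 11 lower. List tests of the dose contrasts were chosen after seeing the data. The count of genes was 17, 15 and 1398 without untreated replicate 1, 2 and 3, 30 without CSH18 replicate 2, and 424 with the serial number covariate, which included 17 mitotic genes.

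At 2 µM, 2 genes passed against untreated. TRIB3 rose by 1.32, and TMIGD1, a dim gene, fell by 2.15. Over the alternatives the difference of TMIGD1 ranged from -3.09 to -1.18. The ATF4 list had a mean of 0.72, with 25 of 28 genes positive and 19 higher when adjusted over the list alone. Its camera adjusted p was 1.5e-30, with an adjusted p = 0.44 with an estimated correlation. Of the 26 lists, 3 others passed with the preset correlation, hypoxia and glycolysis (0.47), MYC ribosome biogenesis (-0.31) and heat shock (-0.26). These had an adjusted p = 0.83, 0.87 and 0.44 with an estimated correlation, and none of their genes passed singly. The hypoxia median of the 2 µM array, 0.49 relative to the untreated mean, lay below the 0.56 of untreated replicate 3. Its MYC target median, -0.27, lay next to the -0.24 of that array, and untreated replicates 1 and 2 lay at 0.11 and 0.17. In a direct test of 6 µM against 2 µM, PLK1 was lower at 6 µM (-1.29) and TMIGD1 higher (2.20), each with a limma adjusted p of 0.040. The mitotic list had a mean of -0.42 in this contrast, with 37 of 43 genes negative, a camera adjusted p of 3.2e-24 and an adjusted p = 0.44 with an estimated correlation. The DNA replication list had 0.41, with an adjusted p of 1.3e-17 and an adjusted p = 0.59 with an estimated correlation. The 2 µM group is 1 array. Untreated arrays and the serial number covariate do not enter the difference of 6 µM minus 2 µM, and alter only the spread behind its test. The 2 µM count of genes against untreated was 0, 0 and 1111 without untreated replicate 1, 2 and 3, and 32 without CSH18 replicate 2 or 3. The 6 µM against 2 µM count was 0, 0 and 84 without untreated replicate 1, 2 and 3, and 8 without CSH18 replicate 2. Without CSH18 replicate 3 neither PLK1 (-0.95) nor TMIGD1 (2.18) passed.

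**Figure D3:**
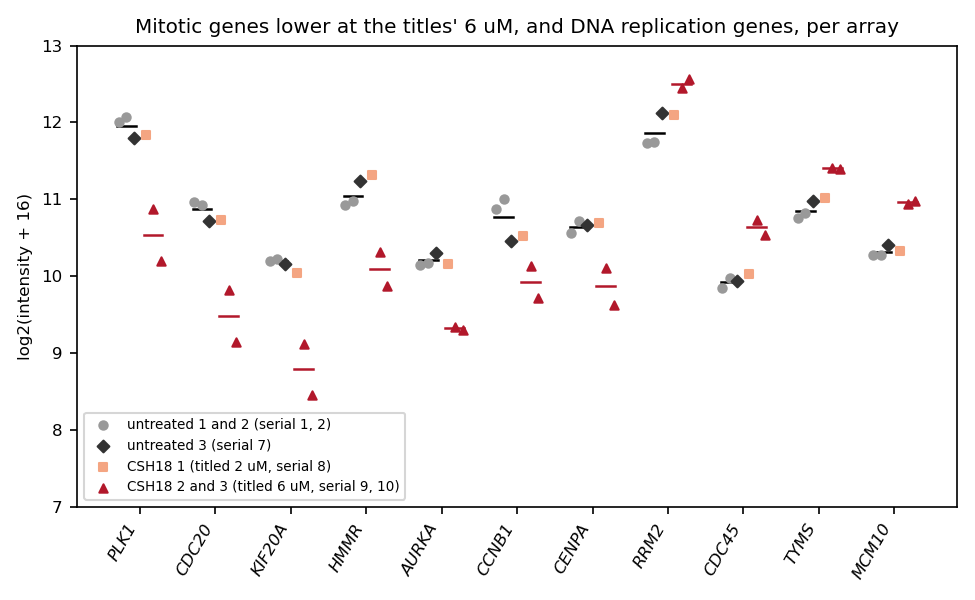
Level on each array, as log2(intensity + 16), of the 7 mitotic genes lower at the titles' 6 µM and of RRM2, CDC45, TYMS and MCM10, of which RRM2 passed. Lines are the means of the 3 untreated arrays (black) and of the 2 arrays at 6 µM (red); the 2 µM array lay near the untreated arrays for PLK1, KIF20A and CDC20.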

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

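The list tests of the dose contrasts and the comparison of the 2 µM array with the untreated arrays were chosen only after the result was seen; the test of random lists was written before.

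PLK1 differed between the titles' doses by -1.29 and TMIGD1 by 2.20 in limma's direct contrast of 6 µM with 2 µM. TMIGD1 was at 4.79 on the 2 µM array and between 6.55 and 7.29 on the other 5 arrays, so its difference rests on that array. Over the alternatives this difference ranged from 1.21 to 3.15. List means that differed between the doses with the preset correlation were 0.24 for the ATF4 list, -0.16 for cholesterol synthesis, -0.31 for hypoxia and glycolysis, 0.41 for DNA replication and -0.42 for mitotic genes, and none passed with an estimated correlation. Among the 37519 probe sets with no gene name here, which the report does not use, 17 passed when all probe sets were tested, 14 higher and 3 lower after CSH18.

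The lower mitotic genes at 6 µM than at 2 µM were weighed against technical explanations. A brightness-dependent scale difference is argued against by random lists matched on mean level, of which 0 of 10000 had a mean as low as -0.42 (lowest -0.097). An odd 2 µM array stays open. Its mitotic list median was 0.029 relative to the untreated mean, within the untreated range of -0.074 to 0.093, but an array of cells that had responded little would lie there too. The 2 arrays at 6 µM lay at -0.29 and -0.39. A difference in dose may be the cause, as may a difference in culture state between these arrays, which no test here separates, and the protocol states a single dose.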

How the results depend on the processing

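The use of serial numbers 7 to 10 alone, and the serial covariate in the dose contrasts, were chosen after seeing the data. No paired analysis was possible because no label pairs the arrays. The second deposited table (the same values) and the olfactory receptor list were not run. For lists and single genes other than TNF and MAPK12, 670 of 799 alternatives kept direction and side of the threshold, 102 lost the call, 22 gained one and 5 turned the sign. Those kept include named falls that passed neither before nor in the alternative. The covariate and serial numbers 7 to 10 alone share the same differences but count separately. The genes and lists were picked by their result before any alternative, so these counts do not measure how firmly the calls hold. Of 17 alternatives each, TNF and MAPK12 turned the sign in 2. The cause was not tested for the following.

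CSH18 against untreated (40 genes) gave 5 genes without the eBayes trend, 70 with robust eBayes and 11 to 1358 leaving out 1 array. Serial numbers 7 to 10 alone had the differences of the covariate fit, from fewer arrays. Welch's test per gene gave 0, with 662 of 14884 genes at unadjusted p under 0.05, a share below 0.05. All probe sets gave 47, 34 higher and 13 lower, against 38 and 2. The serial covariate gave 35 higher and 16 lower. The contrast of 6 µM with untreated (57) gave 5 without trend, 115 robust, 424 with the serial covariate and 15 to 1398 leaving out 1 array. The contrast of 2 µM with untreated (2) gave 13 with offset 1, 1 with offset 64, 0 with quantile normalization, 10 with median centring, 0 without the dimmest 50% of genes, 0 without trend, 13 robust, 19 with the serial covariate and 0 to 1111 leaving out 1 array. The contrast of 6 µM with 2 µM (2) gave 12 with offset 1, 0 with offset 64, 0 with quantile normalization, 0 without the dimmest 50%, 0 without trend, 7 robust, 0 with the mean over probe sets, 85 with the serial covariate and 0 to 84 leaving out 1 array. In that contrast the covariate and the untreated arrays alter only the spread, not the difference. The 9 lists became 0 with an estimated correlation and 6 to 8 leaving out 1 array.

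With the serial covariate, and with serial numbers 7 to 10 alone, MAPK12 turned to -0.11, hypoxia and glycolysis to -0.39 and MYC ribosome biogenesis to 0.043. Leaving out 1 array, the cholesterol list ranged from -0.29 to 0.00093 (without untreated replicate 3), TNF from -0.26 to 0.25 and MAPK12 from 0.19 to 0.50. Dim genes were measured less precisely. The median SE was 0.256 among the dimmest 25% of genes, with 0 past the threshold, and 0.156 among the brightest 25%, with 25.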

Other observations

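The tests with the serial number covariate, the count of genes that set untreated replicate 3 apart, the SE comparison and the splits of genes were chosen only after the result was seen; the random lists, the quantile normalization and the splits of lists were written before.

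Untreated replicate 3 differed from untreated replicates 1 and 2 at 1019 genes in limma, 570 higher and 449 lower, with the spread taken from the other arrays. Of 17 hypoxia and glycolysis genes 14 were higher there, among them HK2 (1.70) and BNIP3 (1.46), as were 7 of 18 cholesterol genes. Of 20 ribosome biogenesis genes, 7 were lower. The list means were 0.97 for hypoxia and glycolysis, 0.48 for cholesterol synthesis and -0.42 for ribosome biogenesis. The ATF4 list was also higher on untreated replicate 3, with a mean of 0.47 and 25 of 28 genes positive. These means rest on 1 array. Genes chosen after their values were seen include the T cell gene THEMIS (2.85) and the transcription factor BCL6 (2.82), which were higher on untreated replicate 3, and IL7R (-2.30), ICOS (-2.05) and CCR4 (-1.38), which were lower.

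Between-array scaling is argued against as the cause of this difference, since quantile normalization left 940 genes, 834 of them shared with the 1019. A batch of hybridisation or culture may be the cause, but no label names one, and the 1019 genes rest on 1 array. Untreated replicate 3 is the only untreated array among serial numbers 7 to 10, so an odd replicate, a batch and another state of the cells cannot be told apart. No biological explanation was tested.

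The rise of the ATF4 list after CSH18 was weighed against the same difference. A brightness-dependent scale difference is argued against by random lists matched on mean level, of which 0 of 10000 had a mean as large as 0.88 (highest 0.20). A difference that goes with the serial numbers may be part or the whole of the cause: the 7 list genes that passed with the covariate were set against untreated replicate 3 alone. For the 9 list genes that lost their call, picked because they passed without the covariate, the mean difference went from 1.13 (mean SE 0.20) to 0.59 (mean SE 0.18), and the calls ended because the difference shrank: 9 of the 9 would have passed the covariate fit with the former difference at its own SE. On untreated replicate 3 itself the list mean was 0.47 above that of untreated replicates 1 and 2, with 25 of 28 genes positive. The list mean of CSH18 minus that array alone, from the covariate fit, was 0.57. Whether that array is unusual stays open.

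Of the 10 splits of the 6 arrays into 3 and 3, 2 gave at least the 40 genes of the real one, and the highest other gave 238. That split set untreated replicates 1 and 2 with CSH18 replicate 2 against the rest, and so many genes point to a structure of the arrays. Whether that structure follows the serial numbers cannot be told. No split of 3 and 3 sets untreated replicates 1 and 2 alone against the rest. Untreated replicates 1 and 2 with CSH18 replicate 1 or 3 gave 0 genes in limma, with 1072 and 1681 at unadjusted p under 0.05. Splits that kept untreated replicates 1 and 2 together gave 1072 to 2940 genes at unadjusted p under 0.05, the real one 1236. Splits that parted them gave 123 to 611. For lists, 1 of the 10 splits, the real one with 9, gave as many, and the highest other gave 5. With 10 splits no share under 0.05 can be reached.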
